A study of Mus musculus with 12 samples.

How the data were processed

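Messenger RNA was sequenced from 12 mouse neuroendocrine thyroid carcinomas. The genotype label placed 7 tumours in the Rb1/Trp53 group and 5 in the Rb1/Trp53/Crebbp group. Per the labels' protocols, RNA was isolated with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were made with the NEBNext Ultra RNA kit. Per the submitters' processing notes, the tools were bcl2fastq 1.8.2, TopHat2 2.0.12 and HTSeq 0.6.1, and the genome build was mm9. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The authors deposited raw read counts per gene, 1 table per tumour, with 23284 genes and 5 summary rows of the counter. The summary rows were left out of library sizes and tests. Reads outside any gene made up 13.1% to 17.6% of each table, and reads aligned to more than 1 place made up 10.9% to 18.5%.

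Total gene counts ranged from 9.11 M to 57.3 M per tumour. At these depths 1 count corresponded to 0.0167 to 0.104 CPM (counts scaled to a library of 1 M), and 3 counts, taken as the floor, to 0.0502 to 0.312 CPM. These limits cover counting error alone. No pair of libraries of a group agreed within sampling noise. Nothing in the labels says whether tumours came from separate mice, so p-values measure the spread between these tumours.

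Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 14989 genes. Libraries were scaled by TMM, and the genotypes were compared with edgeR's robust quasi-likelihood F test with Benjamini-Hochberg adjustment, all 12 tumours entering without covariates. Genes with an adjusted p under 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2.

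Before the data were examined, 28 gene lists were fixed, 26 of which had the 3 tested members needed for a test. They were compared with limma's camera, with a preset inter-gene correlation of 0.01, with camera using an estimated correlation, and with fry. Older symbols were used for 9 members, and 3 members were not found under any symbol tried. List scores are means of z-scored log2 CPM. The distance between tumours was tested with a permutation test of the pseudo-F of Euclidean distances over the 500 most variable genes, in which all 792 splits into 5 and 7 tumours were enumerated. Correlations between scores used 100000 permutations. Python 3 packages were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

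The genes named were also fixed by rule before the data were examined. They are Crebbp, Rb1, Trp53 and Ep300, the 8 called genes with the largest log2 fold change in each direction among those with a mean of at least 1 CPM and a symbol other than a predicted model, the 4 with the smallest p in each direction, and up to 4 called members of each list with the smallest p. Where a list had no called member, the one with the smallest p was taken. Some genes that meet the rule are not reported here and were not searched for values far from their group. Calca, Tg, C530028O21Rik, Ddx3y, Kdm5d and the members of gene families named in the closing part lie outside this rule and were chosen after their values were seen.

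On simulated counts with the means, depths and dispersions of these tumours, in which 200 of 14989 genes were changed, the test recovered 56% of genes changed 2-fold and 89% of those changed 4-fold between the Rb1/Trp53/Crebbp and Rb1/Trp53 groups. Of 148 calls, 2 were false. Each gene was drawn independently of the others, whereas genes of these tumours move together. The false calls therefore do not give the rate in the real data. The alternatives were DESeq2 1.42.0, limma voom with sample weights, 2 other scalings, 2 other filters, a test against a 1.5-fold change, the tumour number as a block, marker scores, Y-linked expression or a surrogate variable from sva 3.50.0 as covariates, and leaving out each tumour. Further alternatives were chosen after seeing the data: 3 tumours left out together, the deepest library thinned, Calca left out, and both marker scores as covariates. Besides the drawn splits of the tumours, all 35 exchanges of 1 tumour between the groups were fitted, which was also chosen after seeing the data. Gene neighbours and current symbols were taken from the RefSeq annotation of GRCm38.p6, in which 14888 tested genes were matched; none of its coordinates are given, since the counts were made on mm9.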

Results

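Gene expression was measured in 12 primary neuroendocrine thyroid carcinomas of a genetically engineered mouse model, to find genes regulated by Crebbp, a histone acetyltransferase and transcriptional coactivator. The labels gave the genotype Rb1/Trp53 for 7 tumours, called RP-labelled here, and Rb1/Trp53/Crebbp for 5 tumours, called RPC-labelled. Gene counts per tumour were 9.11 M to 57.3 M in the RP-labelled group and 9.14 M to 20.5 M in the RPC-labelled group. Calca, the calcitonin gene of thyroid C cells, took 14.5% ± 4.24 (SD, n = 7) of gene counts in RP-labelled tumours and 6.98% ± 4.17 (SD, n = 5) in RPC-labelled tumours, a difference in the share with an exact two-sided permutation p of 0.0164, while the gene test did not call Calca (log2 fold change -1.21 ± 0.50 SE; adjusted p = 0.103).

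The targeted gene was examined first. Crebbp stood at 53.9 ± 4.19 CPM (SD, n = 5) in RPC-labelled and 54.6 ± 20.04 CPM (SD, n = 7) in RP-labelled tumours, a log2 fold change of -0.02 ± 0.20 (SE; edgeR adjusted p = 0.957). RP-labelled replicate 1 held 98.9 CPM, and without it the log2 fold change was 0.19. Total Crebbp counts were therefore not lower in the RPC-labelled tumours. Counts per gene do not show the loss of single exons, and which part of the gene was targeted is not given in the sources used here, so these counts check neither the labels nor the loss of the protein. The same limit holds for Rb1 and Trp53, which are named in the genotype of both groups. Their counts do not show which exons or cells the reads came from, so a difference is not read as regulation of the gene. Every direction below is drawn between groups as labelled. Rb1 had a log2 fold change of 0.37 ± 0.17 (SE; adjusted p = 0.137), and Ep300, the paralogue of Crebbp, one of 0.29 ± 0.17 (SE; adjusted p = 0.252). Trp53 transcripts were lower in all 5 RPC-labelled tumours than in any RP-labelled tumour, at 16.1 ± 4.15 against 28.9 ± 4.70 CPM (log2 fold change -0.84 ± 0.17 SE; adjusted p = 0.00918).

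The whole profiles separated by label. Over the 500 most variable genes the pseudo-F was 4.05, and genotype accounted for 28.8% of the squared distances. No other split of the 12 tumours gave as large a value (exact one-sided permutation p = 0.00126, the smallest the 792 splits can give). The mean distance to the group centroid was 33.5 in RPC-labelled and 34.9 in RP-labelled tumours, a difference not set apart from those of other splits (exact two-sided permutation p = 0.865). The groups were not centred before the splits, so the distance between them enters the spreads of the other splits. This p is therefore not a strict test of equal spread.

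**Figure D1:**
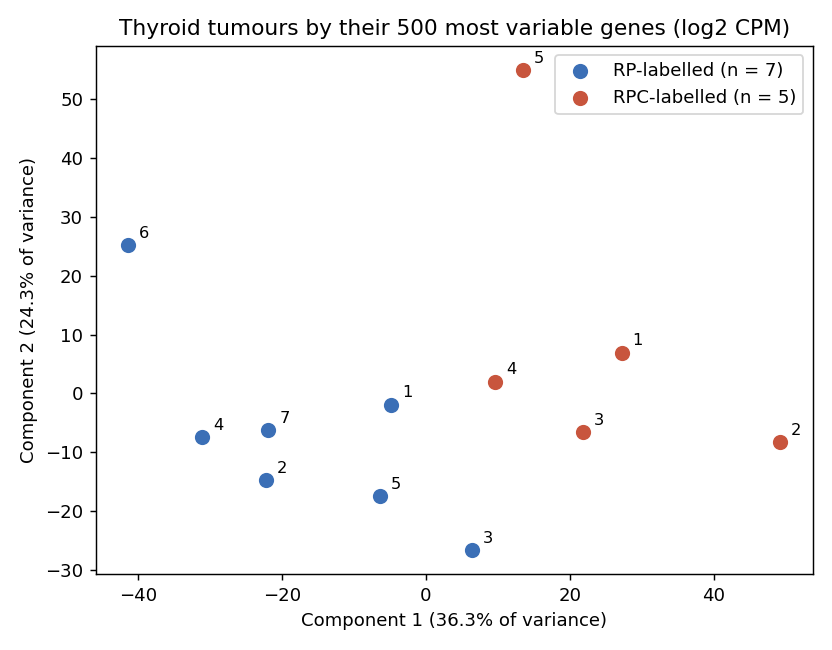
Principal components of log2 CPM over the 500 most variable genes. Each point is a tumour numbered by its replicate, blue for RP-labelled (n = 7) and red for RPC-labelled (n = 5). The groups do not overlap along the first component, and the pseudo-F between them was 4.05.

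Of 14989 genes tested, 1445 were higher and 1291 lower in RPC-labelled tumours (edgeR quasi-likelihood test, adjusted p under 0.05). Among them 474 were higher and 578 lower by at least 2-fold. The ranges of the groups did not overlap for 938 genes, 6.26% of those tested, where chance gives 0.253%. The largest rises were in Krt4, a keratin of stratified epithelium, at 83.6-fold, in the homeobox genes Hoxd8 (49.9-fold), Dmbx1 (34.5-fold) and Hoxd4 (27.7-fold), in Gcg, which encodes proglucagon (24.4-fold), in the fibrinogen gene Fgb (21.4-fold), in the neuronal gene Nsg2 (19.7-fold) and in the splicing factor gene Cwc22 (16.6-fold). The RP-labelled means of Dmbx1 (0.338 CPM), Fgb (0.311 CPM) and Gcg (0.302 CPM) are close to the level of 3 counts, 0.0502 to 0.312 CPM, so the sizes of these 3 rises are uncertain. The Krt4 value came mainly from RPC-labelled replicate 5, at 705.9 CPM against at most 7.06 CPM in the other RPC-labelled tumours, and it was not called without that tumour. The Hoxd8, Hoxd4 and Dmbx1 levels of RPC-labelled replicate 4 lay within the RP-labelled range. Without RPC-labelled replicate 2 the log2 fold changes of Hoxd8, Dmbx1, Hoxd4 and Fgb went from 5.64, 5.11, 4.79 and 4.42 to 4.12, 4.20, 3.50 and 3.59, and that of Gcg went from 4.61 to 3.97 without RPC-labelled replicate 1. Cwc22 had the smallest p of all genes, with 30.5 to 35.5 CPM in the RP-labelled tumours and 293 to 648 CPM in the RPC-labelled tumours (log2 fold change 4.05 ± 0.17 SE; adjusted p = 8.0e-08). Col9a2, Sh3rf3 and Nsg2 followed among higher genes, each higher in all 5 RPC-labelled tumours than in any RP-labelled tumour.

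The largest falls were in Ucp1, the uncoupling protein of brown fat (24.0-fold), Bpifa1, a secreted airway protein (22.6-fold), H2-Q10 (18.1-fold), the fat hormone gene Lep (15.1-fold), Pck1 (14.1-fold), Crygn (13.7-fold), Th, which encodes tyrosine hydroxylase (13-fold), and the lipid droplet gene Plin1 (12.6-fold). The RPC-labelled means of H2-Q10 (0.263 CPM), Lep (0.297 CPM) and Crygn (0.156 CPM, with 0 in replicates 2 and 3) lie within the 0.0502 to 0.312 CPM that 3 counts make in these libraries, so the sizes and ranks of these 3 falls rest on a few counts. Th fell from 19.8 ± 6.01 CPM (SD, n = 7) to 1.48 ± 0.65 CPM (SD, n = 5), a log2 fold change of -3.70 ± 0.34 (SE; adjusted p = 2.8e-04). Upp1, Lrrc36 and Cd55 had the next smallest p among lower genes with a symbol other than a predicted model, and all 3 were lower in each RPC-labelled tumour than in any RP-labelled tumour. Ucp1, Bpifa1, Lep, Pck1 and Plin1 varied widely among RP-labelled tumours, Ucp1 from 0.520 to 156.7 CPM, and Ucp1, Bpifa1 and Lep lost their call when any 1 of RP-labelled replicates 2, 4, 6 and 7 or of RPC-labelled replicates 1 to 4 was left out. Ucp1 and Bpifa1 also lost it without RPC-labelled replicate 5. Pck1 lost it without RPC-labelled replicate 1 or 2, and Plin1 without RPC-labelled replicate 2. The log2 fold change of Bpifa1 went from -4.50 to -3.61 without RP-labelled replicate 7 and to -5.27 without RPC-labelled replicate 1, that of Lep from -3.91 to -3.27 without RP-labelled replicate 2 and to -4.70 without RPC-labelled replicate 5, and that of Crygn from -3.77 to -4.76 without RPC-labelled replicate 1.

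**Figure D2:**
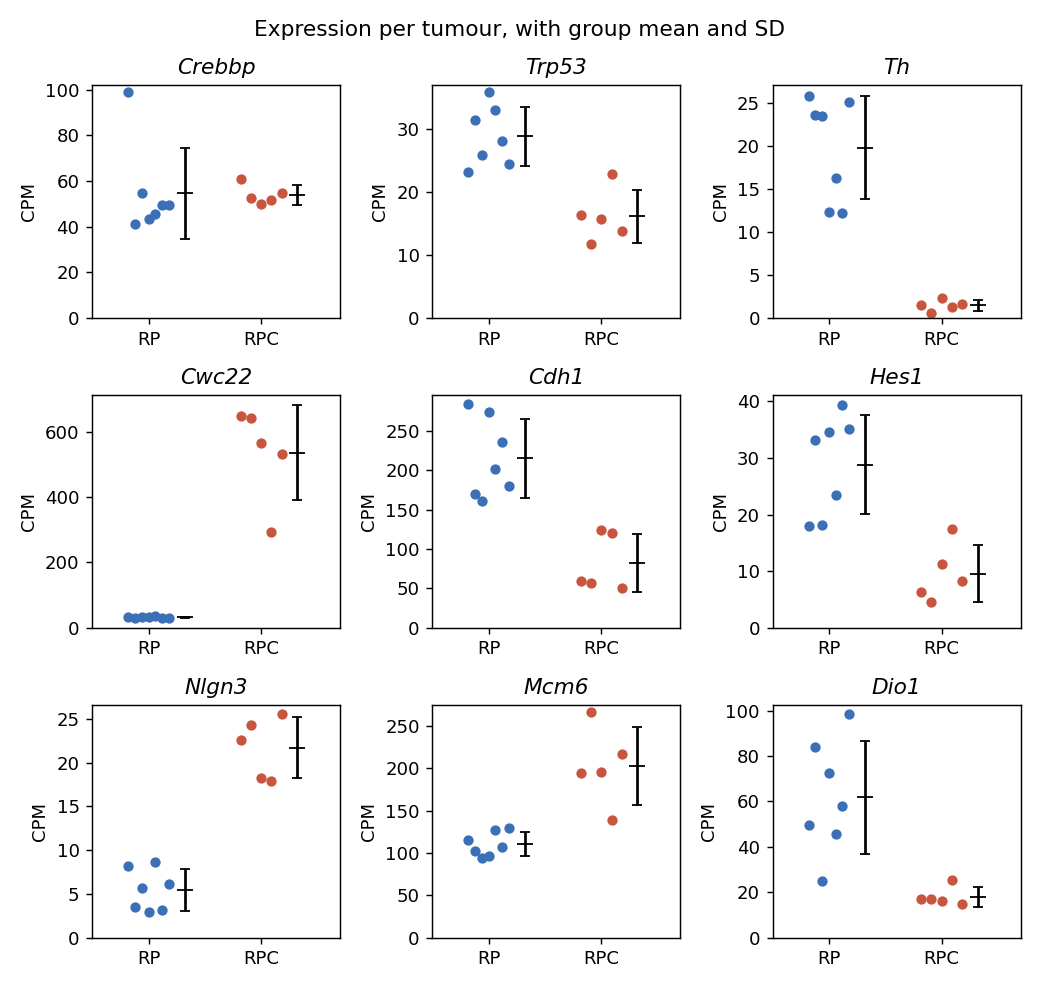
Expression in CPM of 9 named genes, on linear axes from 0. Each point is a tumour, RP-labelled in blue (n = 7) and RPC-labelled in red (n = 5), and the bar gives the group mean and SD. Crebbp overlaps between groups, while Th, Cwc22 and Nlgn3 do not.

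The number of called genes changed with the tumours included, with a marker score as a covariate and with the method. Limma voom with sample weights called 6352 genes. Replicates 1 to 5 of both groups gave 868, or 463 with the tumour number as a block. Leaving out single tumours gave 1074 genes (without RPC-labelled replicate 2) to 3510 genes (without RP-labelled replicate 3). It fell by more than 1.5 times without RP-labelled replicates 2 (1653), 4 (1547) or 6 (1692), and without RPC-labelled replicates 1 (1322), 2, 3 (1782) or 5 (1820). With so few calls left, the loss of calls among list members in the fit with the follicular score, given below, says little about any list. With the thyroid follicular cell marker score as a covariate 5 genes were called, namely Cwc22, Col9a2, Th, Sh3rf3 and C530028O21Rik, and 1608 had an unadjusted p under 0.05. That score differed between the groups, at -0.601 ± 0.603 (SD, n = 5) against 0.430 ± 0.315 (SD, n = 7), with an exact two-sided permutation p of 0.00253.

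Of 26 gene lists tested, 10 passed the camera threshold, 3 as higher and 7 as lower in RPC-labelled tumours. None passed with an estimated correlation, where the smallest adjusted p was 0.442, and 6 passed with fry. Those past it with fry were the cell cycle, hypoxia, neuronal adhesion, epithelial adhesion, follicular and lymphocyte lists. The antigen presentation (fry adjusted p = 0.165), endothelial (0.165), fibroblast (0.211) and adipocyte lists (0.0805) were not past it with fry. The number of lists past the threshold does not set the genotypes apart from other groupings: 37 of 100 splits of the 12 tumours gave 10 or more lists. The counts of called members given for each list below rest on the gene test, which called 18.3% of all tested genes.

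Cell cycle genes and E2F targets were higher. Of 35 members 28 rose and none fell, 34 rose when adjusted over the list alone, and the median fold was 1.86 (camera adjusted p = 2.0e-13; adjusted p = 0.636 with an estimated correlation). The replication licensing genes Mcm6 and Mcm2 rose 1.83-fold and 1.71-fold, Cdt1 rose 1.74-fold, and the G1 cyclin gene Ccne2 rose 2.06-fold. RPC-labelled replicate 4 held the lowest level of all 4 genes in its group. With the follicular marker score as a covariate none of the 28 was called: their median log2 fold change went from 1.02 to 0.38 and its median SE from 0.25 to 0.37, while the list stayed past the camera threshold. Hypoxia and glycolysis genes were also higher, with 9 of 21 members called, all as rises, and 11 rises and 2 falls when adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.636 with an estimated correlation). Pdk1 rose 1.69-fold, Pgk1 1.92-fold, Pkm2 1.45-fold and Pfkl 1.61-fold. With the follicular score as a covariate none of the 9 was called: their median log2 fold change went from 0.71 to 0.47 and its median SE from 0.14 to 0.24, while the list stayed past the threshold (camera adjusted p = 0.0349).

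Genes of neuronal cell adhesion rose in 13 of 32 tested members, with no fall and 16 rises when adjusted over the list alone (camera adjusted p = 6.9e-07; adjusted p = 0.442 with an estimated correlation). The synaptic adhesion gene Nlgn3 rose 3.95-fold, the protocadherin gene Pcdh17 5.12-fold, Slitrk6 2.27-fold and L1cam 1.67-fold. With the follicular marker score as a covariate none of the 13 was called: their median log2 fold change went from 1.18 to 1.09 and its median SE from 0.26 to 0.43. Genes of epithelial adhesion and tight junctions went the other way. Of 35 members 11 fell and 2 rose, or 12 and 2 when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.636 with an estimated correlation). Cdh1, which encodes E-cadherin, fell from 215 ± 49.9 CPM (SD, n = 7) to 82.4 ± 36.6 CPM (SD, n = 5). The tight junction genes Tjp3, Cldn4 and Cldn3 fell 2.14-fold, 2.80-fold and 2.21-fold. With the follicular marker score as a covariate the epithelial list was no longer past the threshold (camera adjusted p = 0.0794) and none of the 11 members was called. Among 18 mesenchymal transition genes Cdh2, the N-cadherin gene, alone rose, by 1.65-fold, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.172). It passed as lower on replicates 1 to 5 of both groups, with the tumour number as a block (0.00277) or without it (0.0102), and with the follicular marker score as a covariate (0.00104). The Cdh2 call was lost without RPC-labelled replicate 2, and the L1cam call without RPC-labelled replicate 1, 2 or 5.

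**Figure D3:**
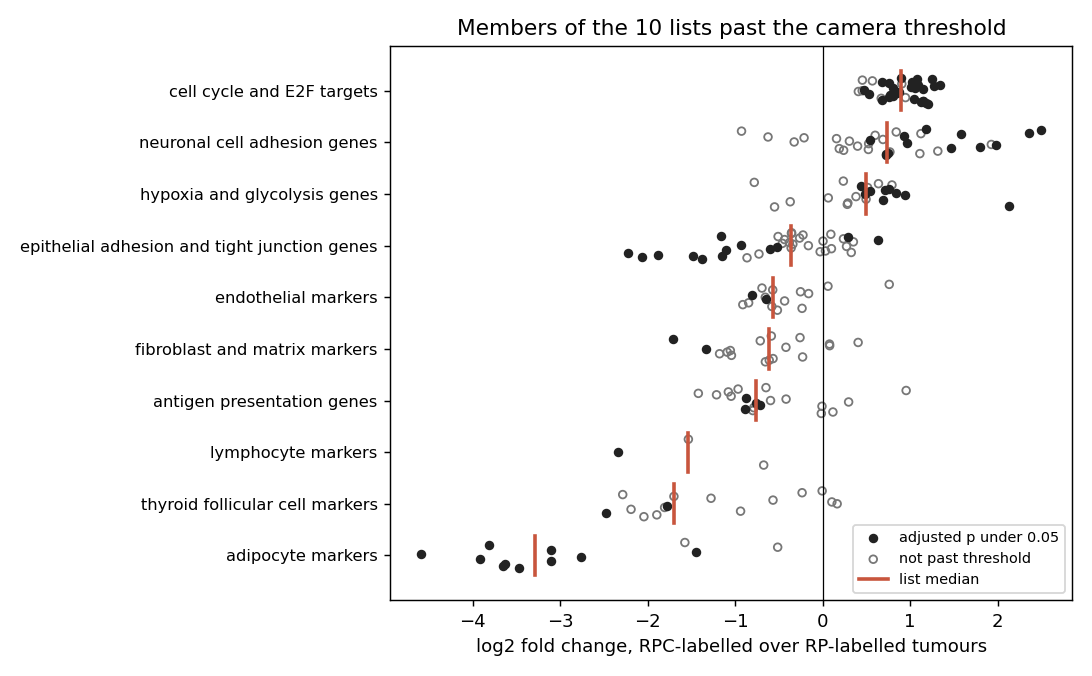
Log2 fold change, RPC-labelled over RP-labelled tumours, of the tested members of the 10 lists past the camera threshold. Filled points passed the gene test, open points did not, and the red bar is the list median. Of the 35 cell cycle members, 28 are filled and all lie to the right of 0.

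Called neuroendocrine identity genes went both ways, while 14 of the tested members had a log2 fold change below 0 and 6 one above 0. Of 20 tested members 4 rose, with Uchl1 at 1.59-fold, Ddc at 2.76-fold and Ncam1 at 1.65-fold among them, and 2 fell, with the prohormone convertase gene Pcsk2 falling 2.61-fold (camera adjusted p = 0.580). Adjusted over the list alone, 4 rose and 4 fell. C cell markers showed rises of Gfra1 (5.34-fold) and Phox2a (1.92-fold) and a fall of Nkx2-1 (1.35-fold) among 12 tested members (camera adjusted p = 0.751). Of 14 tested regulators of small cell cancer subtypes, 3 rose and 3 fell, among them Nfib (2.0-fold higher), Mycl1 (2.88-fold higher) and Yap1 (2.32-fold lower; camera adjusted p = 0.751). Adjusted over the list alone, 2 C cell markers rose and 1 fell, and 4 subtype regulators rose and 3 fell. The Mycl1 call was lost without RPC-labelled replicate 2 (log2 fold change 1.53 to 0.98), the Ncam1 call without RPC-labelled replicate 1 or 2, and the Phox2a call without several tumours, RPC-labelled replicate 2 among them. In the Notch list 5 members fell and 1 rose of 16 tested, or 8 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.159). The Notch target Hes1 fell 3.02-fold, Heyl 2.28-fold and the ligand gene Dll1 2.07-fold, and Hey1 rose 1.54-fold. The Dll1 call was lost without RPC-labelled replicate 2, and the Hey1 call without several tumours, that one among them.

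Among CREB and cAMP response genes 4 of 26 rose and 1 fell, with Pde4b at 2.86-fold, Areg at 4.51-fold and Nr4a2 at 2.0-fold. The list median was -0.15 while camera placed the list as higher (adjusted p = 0.882). Of 26 histone acetylation enzymes and readers, Hdac11 and Hdac7 fell, each by 1.55-fold (camera adjusted p = 0.387). Of 22 p53 targets 3 fell, Btg2, Fas and Bbc3 (camera adjusted p = 0.198). Antigen presentation genes were lower, with 4 of 19 called, Tap2, Psmb10, Tapbp and H2-T23 (camera adjusted p = 0.0191; adjusted p = 0.730 with an estimated correlation), and the list was not past the threshold without RP-labelled replicate 3 (adjusted p = 0.0729), RP-labelled replicate 5 (0.0638) or RPC-labelled replicate 4 (0.0665), nor with limma voom (0.0690) or the stromal and immune marker score as a covariate (0.508). Adjusted over the list alone, the calls were 4 rises and 1 fall among CREB genes, 1 fall among histone acetylation genes, 3 falls among p53 targets and 4 falls among antigen presentation genes. Interferon-stimulated genes (2 of 22 lower, Irf1 and Cxcl10; camera adjusted p = 0.172), cholesterol synthesis genes (2 of 19 higher, Lss among them; 0.389) and the list of engineered and related loci (1 of 6 lower; 0.751) did not pass. Adjusted over the list alone they had no call, 1 rise and 1 fall in that order. The interferon list passed as lower on replicates 1 to 5 with the block (0.0109) or without it (0.00839). The calls of Hdac7, Fas, Bbc3, H2-T23, Irf1 and Cxcl10 were lost without several tumours, RPC-labelled replicate 2 among them in each case. That of Nr4a2 was lost without RP-labelled replicate 2 or 4 or RPC-labelled replicate 1 or 5, that of Psmb10 without RPC-labelled replicate 1 or 2, and those of Tapbp and Lss without RPC-labelled replicate 1.

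Markers of other cell types also moved with the labels. Adipocyte markers fell in 10 of 12 members, with a median fold of 9.76 (camera adjusted p = 4.5e-04; adjusted p = 0.679 with an estimated correlation), and Fabp4 and Retn fell 8.59-fold and 8.57-fold. With the follicular marker score as a covariate the adipocyte list missed the threshold (camera adjusted p = 0.0883) and its median log2 fold change went from -3.29 to -1.75, and on replicates 1 to 5 with the block it was -1.83. The adipocyte scores of RP-labelled replicates 1 and 3 lay within the RPC-labelled range, and those of RP-labelled replicates 2, 4, 6 and 7 were the highest. The Fabp4 and Retn calls were lost without RPC-labelled replicate 1 or 2. Thyroid follicular cell markers were lower with a median fold of 3.25, although 2 of 15 members, Dio1 and Tshr, passed the gene test and 7 did when adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.636 with an estimated correlation). Thyroglobulin, Tg, singled out after its values were seen as the most abundant follicular transcript, stood at 6866 ± 2607 CPM (SD, n = 7) in RP-labelled and 1667 ± 2226 CPM (SD, n = 5) in RPC-labelled tumours (adjusted p = 0.122), with 1482 CPM in RP-labelled replicate 3 and 5488 CPM in RPC-labelled replicate 4. Endothelial (2 of 15 lower, Esam and Emcn; camera adjusted p = 0.00926), fibroblast (2 of 17 lower, Thy1 and Pdgfra; 0.0258) and lymphocyte markers (1 of 3 lower, Cd79a; 0.0393) passed as lower, with adjusted p of 0.730, 0.730 and 0.442 with an estimated correlation. Each of these 3 lists missed the threshold without RP-labelled replicate 3, at adjusted p of 0.0555, 0.128 and 0.0555 in that order. The fibroblast list also missed it without RP-labelled replicate 5 (0.0891), RPC-labelled replicate 2 (0.0546) or RPC-labelled replicate 4 (0.134), and the lymphocyte list without RPC-labelled replicate 4 (0.0678). With limma voom the fibroblast and lymphocyte lists missed it, both at 0.110. The calls of Tshr, Pdgfra, Esam and Emcn were lost without several tumours, RPC-labelled replicate 2 among them in each case. Adjusted over the list alone, 11 adipocyte, 1 fibroblast, 2 lymphocyte and no endothelial markers fell.

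Macrophage markers (none of 16 called, Csf1r with the smallest p; camera adjusted p = 0.159), airway and squamous epithelium markers (1 higher and 2 lower of 14, Dnaic1 among the lower; 0.172), Schwann cell and nerve markers (1 higher, Prph, and 2 lower, S100b among them, of 8; 0.655), parathyroid and thymus epithelium markers (Foxn1 lower, of 6; 0.398) and skeletal muscle markers (none of 15, Pvalb with the smallest p; 0.882) did not pass. Adjusted over the list alone, 2 airway markers rose and 4 fell, 1 Schwann cell marker rose and 2 fell, 1 parathyroid and thymus marker fell, and no macrophage or muscle marker was called. The S100b call was lost without RPC-labelled replicate 1 or 2. The macrophage list passed as lower on replicates 1 to 5 with the block (0.00120) or without it (0.00153). Red blood cell markers had 2 tested members, neither called, with Slc4a1 at an adjusted gene p of 0.530. Of the sex-linked genes Xist was tested and not called (adjusted p = 0.619).

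Scores of the lists were then compared across tumours after centring within each genotype, over 10 pairs of a marker score with a pathway score. The follicular marker score and the cell cycle score had r = -0.45 (permutation p = 0.217; adjusted p = 0.544) and rho = -0.25 (permutation p = 0.488; adjusted p = 0.867), and without the 2 tumours farthest from the median r was 0.39. The follicular and epithelial scores had r = 0.49 (permutation p = 0.156; adjusted p = 0.521) and rho = 0.49 (permutation p = 0.140; adjusted p = 0.351), and without the 2 farthest tumours r was -0.01. The largest of the 10 values was that of the stromal and immune score with antigen presentation genes, at r = 0.74 (permutation p = 0.0125; adjusted p = 0.125), rho = 0.78 (permutation p = 0.0119; adjusted p = 0.119) and r = 0.66 without the 2 farthest tumours. None of the 10 pairs passed after adjustment. Uncentred, where the difference between genotypes enters, 5 of the 10 passed, each at an adjusted p of 0.0116: the follicular score with the cell cycle (r = -0.78), neuronal adhesion (r = -0.73), hypoxia (r = -0.74) and epithelial scores (r = 0.76), and the stromal and immune score with antigen presentation (r = 0.81). Without the 2 farthest tumours these were -0.48, -0.72, -0.76, 0.53 and 0.66 in that order.

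**Figure D4:**
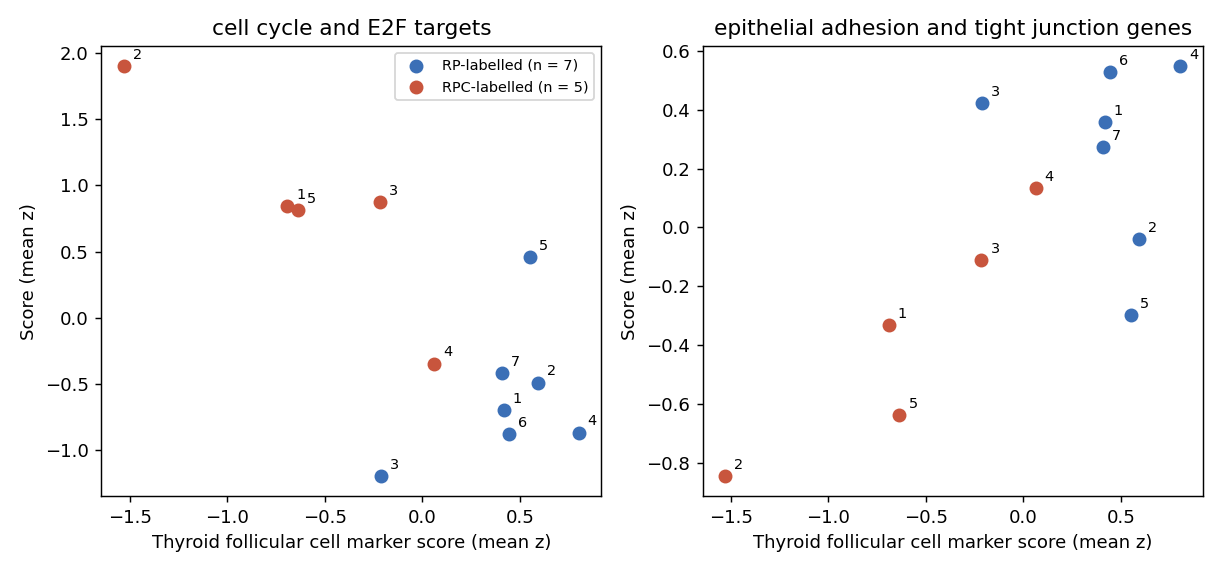
Scores (mean z of log2 CPM) of the cell cycle list and of the epithelial adhesion list against the thyroid follicular cell marker score, uncentred. Each point is a tumour numbered by its replicate, blue for RP-labelled (n = 7) and red for RPC-labelled (n = 5). RPC-labelled replicate 4 lies nearest to the RP-labelled tumours in the cell cycle panel, and its Tg level was 5488 CPM.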

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

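Values in this part lay far from the rest of their group, by Dixon's ratio of the gap to the nearest tumour over the group's range. Chance flags about 1 in 20 groups, or 11.8 of the 236 examined, and 23 values were found. RP-labelled replicate 3 held 7 of them, RPC-labelled replicates 2 and 4 held 4 each and RP-labelled replicate 5 held 3. No explanation is weighed for them here.

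RP-labelled replicate 3 was the highest of 7 for Cdh2 (6.02 log2 CPM, the nearest at 5.35), Btg2 (8.64 log2 CPM), H2-T23 (7.34 log2 CPM) and the CREB and cAMP response score (0.837). It was the lowest for Cd55 (5.32 log2 CPM), Tshr (0.99 log2 CPM) and the follicular marker score (-0.213). RP-labelled replicate 5 was the deepest library, at 57.3 M gene counts against at most 18.9 M in the others of its group. It was also highest for Dmbx1 (0.20 log2 CPM) and lowest for Tjp3 (4.99 log2 CPM). RP-labelled replicate 1 was highest for Crebbp (6.63 log2 CPM, the nearest at 5.78), and RP-labelled replicate 7 for Hey1 (3.20 log2 CPM).

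Among the 5 RPC-labelled tumours, replicate 4 was lowest for Cwc22 (8.20 log2 CPM, the nearest at 9.05), H2-Q10 (-2.32 log2 CPM) and Hdac7 (5.50 log2 CPM) and highest for Dio1 (4.68 log2 CPM). Replicate 2 was lowest for Lrrc36 (-1.37 log2 CPM), Heyl (0.89 log2 CPM), Esam (2.11 log2 CPM) and the cholesterol synthesis score (-0.525). H2-Q10 in replicate 4 stood at 0.0888 CPM, the level of 1 count in that library. Lrrc36 in replicate 2 stood at 0.2749 CPM, the level of 3 counts there, so these flags rest on a few counts. Replicate 5 was highest for Krt4 (9.46 log2 CPM, the nearest at 2.84) and lowest for Btg2 (6.21 log2 CPM), and replicate 1 was lowest for the Schwann cell and nerve score (-0.412).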

How the results depend on the processing

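The fits with 3 tumours left out (RP-labelled replicates 1 and 6 and RPC-labelled replicate 5), with the deepest library thinned, with Calca left out, and with both marker scores were chosen after the data were seen. The cause of a change was not tested unless stated. The separation of the genotypes was rerun on 2000 or all filtered genes, with Spearman distance, without cell type marker and sex-linked genes, and without each tumour. It stayed past its threshold in all of these, with a pseudo-F of 3.11 to 4.70 when single tumours were left out. It was not rerun with a marker score as a covariate, on replicates 1 to 5 or with 3 tumours left out. With DESeq2 2035 genes were lower. It called 4082 in all. Other scalings, filters and the remaining covariates gave 1930 to 3446. Limma voom with sample weights called 6352 genes, 3290 higher and 3062 lower. The test against a 1.5-fold change, which is stricter by construction, called 153, 107 higher and 46 lower. On replicates 1 to 5 of both groups 868 genes were called, 480 higher and 388 lower, with fewer tumours. With the tumour number as a replicate block on those tumours 463 were called, 244 higher and 219 lower. Same-numbered tumours had correlations of -0.06 to 0.16, and 1 of the 5 RPC-labelled tumours correlated best with its own number, so the numbers are not treated as pairs. With the follicular score 5 genes were called, 3 higher and 2 lower; with both scores 3, 2 higher and 1 lower; with 3 tumours left out 1065, 491 higher and 574 lower. Leaving out single tumours gave 1074 (without RPC-labelled replicate 2) to 3510 genes (without RP-labelled replicate 3), 557 to 1800 higher and 517 to 1710 lower. The lists past the threshold numbered 6 with both scores, 0 with camera and an estimated correlation (2 at an unadjusted p under 0.05), 6 with fry, 7 with voom, 7 with the stromal and immune score, 11 with the follicular score, 12 on replicates 1 to 5 with or without the block, 12 with 3 tumours left out, 9 with the stricter filter, and 6 (without RP-labelled replicate 3) to 12 (without RP-labelled replicate 7 or RPC-labelled replicate 5) when single tumours were left out. The mesenchymal, interferon and macrophage lists gained a call as lower on replicates 1 to 5 (both fits), with the follicular score, with 3 tumours left out and without RP-labelled replicate 7, and the mesenchymal and macrophage lists also without RPC-labelled replicate 5. The cholesterol and skeletal muscle lists gained one as higher with the follicular score and with both scores, and the parathyroid and thymus list one as lower with both scores.

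The Crebbp log2 change turned to 0.19 with voom, 0.0054 with the replicate block, 0.12 with Y-linked expression as a covariate and 0.20 with 3 tumours left out, and ranged from -0.077 (without RP-labelled replicate 2) to 0.19 (without RP-labelled replicate 1) when single tumours were left out. None of these was called. The difference in spread within genotypes ranged from -8.61 to 1.497 when single tumours were left out, and was not past the threshold in any fit. Other changes of direction concerned genes and lists that were not called in that alternative. With voom they were the neuroendocrine list (median -0.017) and the skeletal muscle list (-0.86). With the follicular score they were Ep300 (-0.048), Tshr (0.041), Pvalb (0.11), and the lists of engineered loci (-0.11), neuroendocrine genes (-0.12), C cell markers (-0.17), subtype regulators (-0.035), CREB genes (-0.16) and histone acetylation genes (0.024). With the stromal and immune score they were the mesenchymal (0.17), interferon (0.50), fibroblast (0.029), macrophage (0.36) and skeletal muscle (-0.47) lists; the fibroblast and macrophage markers are part of that score. With both scores they were Pdgfra (0.41), Pvalb (0.29), and the lists of engineered loci (-0.080), neuroendocrine genes (-0.060), mesenchymal genes (-0.13), subtype regulators (-0.091), histone acetylation genes (-0.015), p53 targets (0.027), fibroblast (0.24) and endothelial markers (-0.0087). The remaining ones were Pvalb on replicates 1 to 5 (1.23), the CREB list with Y-linked expression (-0.14), and the C cell list with 3 tumours left out (-0.0021), with Calca left out (-0.28) and without called members held by another list (-0.26). For lists the direction is camera's and the value is the median log2 change, and these can differ in sign. When single tumours were left out Pvalb ranged from -3.99 to 1.27, the CREB list from -0.22 to 0.12, the skeletal muscle list from -3.29 to 2.96 and the C cell list from -0.39 to -0.033. Over all lists and all genes that meet the naming rule, alternatives other than leaving out a tumour kept direction and side of the threshold 1571 times, lost a call 375 times, gained one 23 times and turned direction 31 times; leaving out a tumour did so 1206, 157, 5 and 8 times. Depth limits low genes most: 3 counts equal 0.312 CPM in the shallowest library.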

Other observations

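The gene families in this paragraph, the exchanges of single tumours, the test on neuroendocrine and C cell markers, the test of the chromosome of the 108 genes and the fits with both marker scores or with 3 tumours left out were chosen after the data were seen. Families were defined by the form of the gene symbol, and 8 of 24 passed camera with the preset correlation and none with an estimated one (smallest adjusted p = 0.627). GABA receptor genes alone among the 8 were higher, with 3 of 14 called, Gabra4 and Gabrq among them (camera adjusted p = 0.0240; adjusted p = 0.627 with an estimated correlation). Tubulin genes rose in 5 of 15 members, Tubb1, Tuba1a and Tuba1c among them, without passing (0.0677), and glutamate receptor genes rose in 6 of 16 and fell in 1 without passing (0.140). Claudin genes fell in 5 of 15 and rose in 2 (0.0138; 0.627). Chemokine genes and their receptors fell in 6 of 29, with Ccl11, Cxcl11 and Cxcl16 among them (0.0114; 0.689). The other families past the preset threshold were all lower: ribosomal proteins (1 of 77 called; 3.2e-05; 0.786), the mitochondrial respiratory chain with ATP synthase (1 of 72; 0.00428; 0.812), MHC class I and II genes (5 of 20; 0.00428; 0.627), interleukins and receptors (6 lower and 1 higher of 44; 0.0240; 0.627) and complement and coagulation genes (7 lower and 3 higher of 22; 0.0374; 0.627).

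RP-labelled replicate 1 was the only tumour with Y-linked expression, with 1032 counts of Ddx3y and 5.83 CPM of Xist. RP-labelled replicate 6 held 0 counts of Ddx3y and Kdm5d and 2.52 CPM of Xist, while the other 10 tumours held 1802 to 3183 CPM of Xist. All 5 RPC-labelled tumours expressed Xist. The sex of the mice was not given, so its effect on the comparison was not tested directly. With Y-linked expression as a covariate, which does not mark RP-labelled replicate 6, 3446 genes were called, without RP-labelled replicate 1 3328, without RP-labelled replicate 6 1692, and without both and RPC-labelled replicate 5 1065.

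The number of called genes is not explained by an arbitrary grouping of the tumours, and the number of lists is not distinguished from one. Of 100 splits of the 12 tumours, 1, the real one, gave 2736 or more genes, and the highest of the other 99 gave 0. Those draws held few near neighbours of the real split. Among all 35 exchanges of 1 tumour per group, 25 called no gene, but exchanging RPC-labelled replicate 4 with RP-labelled replicate 3 called 2404, with RP-labelled replicate 1 it called 1685 and with RP-labelled replicate 5 it called 1369. With RP-labelled replicates 2, 4, 6 and 7 it called 0. Exchanging RPC-labelled replicate 5 with RP-labelled replicate 1 called 129, and the remaining 6 exchanges with any call gave 1 to 8. On the first component RPC-labelled replicate 4 (9.62) was the lowest of its group and RP-labelled replicates 1 (-4.80), 3 (6.46) and 5 (-6.34) were the highest of theirs, so the exchanges with most calls were those between tumours at the facing edges of the 2 groups. Reads aligned to more than 1 place made up 15.9% to 18.5% in RP-labelled replicates 2, 4, 6 and 7. They made up 10.9% to 14.1% in RP-labelled replicates 1, 3 and 5 and 11.1% to 14.6% in RPC-labelled tumours. Replicates 2, 4, 6 and 7 were not left out together, so how much of the difference by label rests on them was not tested. For lists, 37 of the 100 splits gave 10 or more, with a highest other of 15, so chance cannot be excluded for the number of lists.

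The first pattern is the rise of cell cycle genes. A candidate explanation is a lower share of non-tumour cells, which would raise every transcript of the tumour cells together. The median log2 change of 32 neuroendocrine and C cell markers was -0.22. It lay below the 0.89 of the cell cycle list by 1.11, more than the markers' SD of 0.97. That argues against a lower share of non-tumour cells as the whole cause only if the genotype leaves these markers unchanged. Members of both marker lists were called in both directions, so this condition is in doubt and the test does not settle the question. Adding the follicular and stromal scores as covariates left 0.318 of the median change of the 28 called members. That change went from 1.02 (median SE 0.25) to 0.32 (median SE 0.40), so the calls ended because it shrank and its error grew. The share left lies under the lower of the bounds given below for the second pattern. By that bound the test came out for non-tumour cell content, as measured by these scores. The shrinkage went with the follicular score, which alone left 0.377 with none called, while the stromal and immune score alone left 0.914 with 11 called. But the follicular score itself differs between the genotypes, so this covariate can also remove a genotype difference and the test cannot name a cause. With it 5 of all 14989 genes were called. Its relation to the cell cycle score within genotypes was not past the threshold (r = -0.45, permutation p = 0.217). Without the 2 tumours farthest from the median that r was 0.39. An effect of the genotype therefore stays open.

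The second pattern is the fall of epithelial adhesion and tight junction genes. With the stromal and immune score as a covariate the 11 called members kept 1.11 of their median change and 9 stayed called. That is above the bound of 0.75 set beforehand. Fewer stromal and immune cells would hardly lower epithelial genes, so this outcome was likely in advance and no conclusion is drawn from it. Fewer thyroid follicular cells, which are epithelial, cannot be told apart from a change in the tumour cells: with the follicular score as a covariate 0.592 of the change was left, from -1.17 (median SE 0.26) to -0.69 (median SE 0.29), between the bounds of 0.5 and 0.75 set beforehand. None of the 11 was then called, as the change shrank and its error grew.

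The third pattern is the 108 genes set apart completely by at least 4-fold, 73 higher and 35 lower, among them Cwc22. A knockout allele made in another strain may carry flanking DNA, which can hold only genes near Crebbp. Of the 108 genes 3 lie on its chromosome and 105 elsewhere, so such a segment cannot hold most of the pattern. The share was 2.78%, against a median of 2.78% and a 95th percentile of 6.48% in random sets matched on expression. With so many genes elsewhere that share was bound to be small, so it tests nothing further. Beside Crebbp itself 18% of 50 tested genes were called, 10 before it, where the chromosome ends, and 40 after it, with 1 gene of the pattern among them, against a median of 18% and a 95th percentile of 28% over 286 windows of 50 genes, which shows no excess there and does not exclude a segment for that gene. Members of the pattern lay within 5 tested genes of each other in 10 pairs, against a median of 4 and a 95th percentile of 7 in 10000 random sets matched on expression, which is consistent with strain segments elsewhere in the genome but also with neighbours that are regulated together or share reads, and 3 of the 10 pairs moved in opposite directions. Strain background and an effect of the genotype therefore both stay open for this pattern.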
